A study of Danio rerio with 4 samples.

How the data were processed

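Droplet-based single-cell RNA libraries (10x Genomics 3-prime v3.1 chemistry) were made from the whole kidney marrow, the main blood-forming tissue of adult zebrafish. There were 2 libraries from wild type fish and 2 from their siblings heterozygous for a nonsense allele of rad21a, 1 of the genes for the cohesin subunit Rad21. Each library came from a pool of 2 to 4 fish, so the library is the replicate and single cells are not. Nothing in the sources used here says that pools or replicate numbers were processed as separate batches, or that the pools of the genotypes were paired.

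The deposited matrices hold raw UMI counts per gene and cell barcode (counts of unique molecular identifiers), which per the file headers came from Cell Ranger. The submitters' processing notes name Cell Ranger 6.0.1 and genome build GRCz11. The annotation release and the read filters are not given in the sources used here. The values are whole numbers over 26573 gene features, and every barcode holds at least 500 UMIs.

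Barcodes with at least 200 detected genes and at most 10% of UMIs from mitochondrially encoded genes were kept. Doublets were marked in each library with Scrublet (in scanpy 1.11.5, automatic threshold) and removed. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components and the 15 nearest neighbours of each cell were used for Leiden clustering (leidenalg 0.10.2) at resolution 1, without batch integration. This gave 33 clusters. A cluster took the class whose markers scored highest in it if at least 3 of them were detected, the score was at least 0.3 (no cluster failed on the score) and its 10 leading genes did not go against the name; otherwise it stayed unnamed. The classes are therefore HSPC-like (haematopoietic stem and progenitor cells), erythroid-like and so on. T and NK cells were joined as 1 class after the data were seen, because 1 cluster held markers of both.

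Counts were summed per library over all kept cells and over each class with at least 50 cells in every library, which gave 8 fits, each with 2 libraries per genotype. Genes were tested with the edgeR 4.0.16 quasi-likelihood F test (TMM normalization, filterByExpr, Benjamini-Hochberg adjusted p under 0.05; R 4.3.3). Log2 fold changes are heterozygous over wild type. The standard error (SE) given with them was derived from the edgeR test, as the absolute log2 fold change over the square root of F. It therefore restates that test and is no separate measure of spread. Levels are given per library as CPM, UMI counts scaled to a common library total. A set of 25 gene lists was tested with limma 3.58.1 camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a class; an estimated correlation and fry were alternatives. fry asks whether the genes of a list move, on balance, one way, and does not compare a list with other genes. Lists of class markers were tested in the same way, apart from the 25. Counts of list members that passed are those of the edgeR fit. Shares of classes were compared with a two-sided exact permutation test, which with 2 against 2 libraries cannot give a p below 0.333. Differences of the genotype effect between a pair of classes were tested with the class by genotype term of an edgeR fit that had library and class as covariates.

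The rule for named genes was: rad21a and the other cohesin genes; in each fit, among genes past the adjusted p, with a mean of at least 20 CPM and with both heterozygous libraries on the same side of both wild type libraries, up to 8 per direction with the largest fold change and a symbol that is not a clone or locus name; and up to 4 members with the smallest p of the lists discussed. Genes of a count of 5 or fewer are named whatever their symbol. These rules, the 25 lists, the marker lists and the tests were fixed before the data were examined; that the 3 lists with the smallest p of each fit are discussed was decided later. Because edgeR passed few genes, the same rule was also applied to DESeq2 1.42.0, a choice made after the data were seen. Choices added after the data were seen also include 3 lists for the closing part and 1 version of the ribosomal list. The ribosomal list was drawn by symbol, and its 92 symbols include genes of kinases and binding proteins. The added version leaves these out (79 symbols). Ribosomal members named below come from it, while counts and tests are those of the full list. Also added were the alternatives without clusters held almost wholly by 1 library or without clusters of low UMI count. Others were the medians of lists with at least 500 genes per cell, and libraries left out in the tests of differences between classes.

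Alternatives were DESeq2, RLE normalization, no filter on low counts, the replicate number as a block, summed counts thinned to equal depth and doublets kept. Others were at least 500 genes per cell, all deposited barcodes, Leiden resolutions of 0.5 and 2 and a class for each cell from its own marker score. The last were cells thinned to 601 UMIs, shares without erythroid-like cells, edgeR on cell numbers, and each library left out in turn. With doublets kept, at least 500 genes per cell, all deposited barcodes or thinned cells, the cells were clustered and named anew. A class there need not hold the same cells as in the main setting. With doublets kept and with all deposited barcodes, some clusters stayed unnamed because their score was low.

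The steps were tested on simulated data made with the depths and spreads of these libraries. In the fits of single classes and of all kept cells, edgeR found 2.99% to 20.9% of genes changed 2-fold, 64.2% to 88.1% of those changed 4-fold and 84.9% to 97.0% of those changed 8-fold, and 6.03% to 19.9% of its calls were genes that had not been changed. A simulated list of 40 genes shifted by 1 on the log2 scale was called in all 8 fits by camera at a correlation of 0.01, in 0 with an estimated correlation (adjusted p from 0.115 to 0.443) and in 4 by fry. An unchanged list was called by camera in 1 fit, that of neutrophil-like cells. Each simulated gene was drawn independently, so these lists do not show how camera behaves with genes that vary together.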

Results

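Transcripts were counted in single cells of whole kidney marrow from adult zebrafish in 4 libraries, 2 wild type and 2 rad21 heterozygous, each a pool of fish. Wild type replicates 1 and 2 held 11812 and 13673 barcodes with 68779389 and 69306974 UMIs, and heterozygous replicates 1 and 2 held 8478 and 11374 barcodes with 66956997 and 78475641 UMIs. The median UMI count per barcode was 2189 and 2377 in wild type and 5393.5 and 4460 in heterozygous libraries. After filtering, 10292, 11589, 7661 and 9932 cells were kept, with a median of 2838, 2931, 6035 and 5270.5 UMIs. Under 200 genes were detected in 306, 369, 135 and 229 barcodes, over 10% mitochondrial UMIs were found in 1245, 1622, 710 and 911, and doublets made up 0.847%, 2.00%, 1.18% and 3.63% of barcodes, fewer than the 9.45%, 10.9%, 6.78% and 9.10% expected at 0.8% per 1000 barcodes. Sets of 4 values are given in this order throughout: wild type replicates 1 and 2, then heterozygous replicates 1 and 2.

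The marrow held HSPC-like, erythroid-like, thrombocyte-like, neutrophil-like, macrophage-like, B-cell-like and T/NK-like cells, which are compared below, and a few dendritic-like, endothelial-like and kidney-tubule-like cells. A further 5.25%, 9.22%, 6.64% and 4.52% of kept cells fell in 6 unnamed clusters. Clusters 20 (neutrophil-like) and 32 (macrophage-like) were held almost wholly by heterozygous replicate 1. Cluster 20 made up 5.36% of its kept cells and cluster 32 made up 9.16%, against 0.0201% each in heterozygous replicate 2. Clusters 5 (neutrophil-like) and 11 (erythroid-like) had median UMI counts of 619 and 673 per cell. Cluster 5 held 9.06%, 9.11%, 0.365% and 2.77% of kept cells, and cluster 11 held 14.7%, 11.4%, 2.17% and 3.40%. Macrophage-like cluster 25, also of low UMI count (median 912.5), held 2.322%, 2.356%, 5.065% and 1.329%.

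The first question was whether the mutated gene itself was expressed at a lower level. The rad21a transcript (ENSDARG00000006092), which encodes the kleisin subunit that closes the cohesin ring, was lower in both heterozygous libraries than in both wild type libraries in all kept cells and in each of the 7 classes. Over all kept cells it stood at 88.6 and 90.4 CPM in wild type and 51.6 and 41.4 CPM in heterozygous libraries, 52.0% of the wild type mean (log2 fold change -1.03, SE 0.18, n = 2 libraries per genotype). The level was highest in thrombocyte-like cells, at 212 and 196 CPM against 107 and 105 CPM (-1.03), and the fold change was strongest in macrophage-like cells, at 120 and 102 CPM against 50 and 41.9 CPM (-1.32, 41.3% of wild type). HSPC-like cells held 70.5 and 68.8 CPM against 39.7 and 28.9 CPM (-1.23, 49.3%). The change was smallest in erythroid-like cells, at 55.1, 72.95, 39.7 and 43.1 CPM (-0.96, 64.6% of wild type), and in T/NK-like cells (-0.97). It stood at -1.12 in neutrophil-like and -1.15 in B-cell-like cells. Fold changes come from the TMM-normalized fit and percentages from CPM, so they need not match.

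Adjusted over all genes of a fit, rad21a did not pass with edgeR in any of the 8 fits (adjusted p = 0.913 over all kept cells, 0.423 in HSPC-like cells). With DESeq2 it passed in all kept cells (adjusted p = 0.00811), HSPC-like (0.0234), erythroid-like (0.0319) and macrophage-like cells (0.00645), not in the other 4 fits. Adjusted over its 8 fits alone, a test added after the data were seen, the edgeR p lay between 0.00281 and 0.0038. The 3-prime tag counts transcripts and does not show the stop allele itself. Among the other cohesin genes over all kept cells, the ring subunits smc1al and smc3 had log2 fold changes of -0.10 and 0.15, the loader genes nipbla and nipblb -0.01 and 0.06 (both change sign without heterozygous replicate 1, to 0.10 and -0.04), and ctcf 0.22. The largest values were those of the acetyltransferase gene esco2 (0.61) and of stag1a (0.49) and stag1b (0.46), which were above both wild type libraries. With edgeR and 20 members tested, 1 (rad21a) passed adjusted over the list alone, and 0 passed over all genes.

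**Figure D1:**
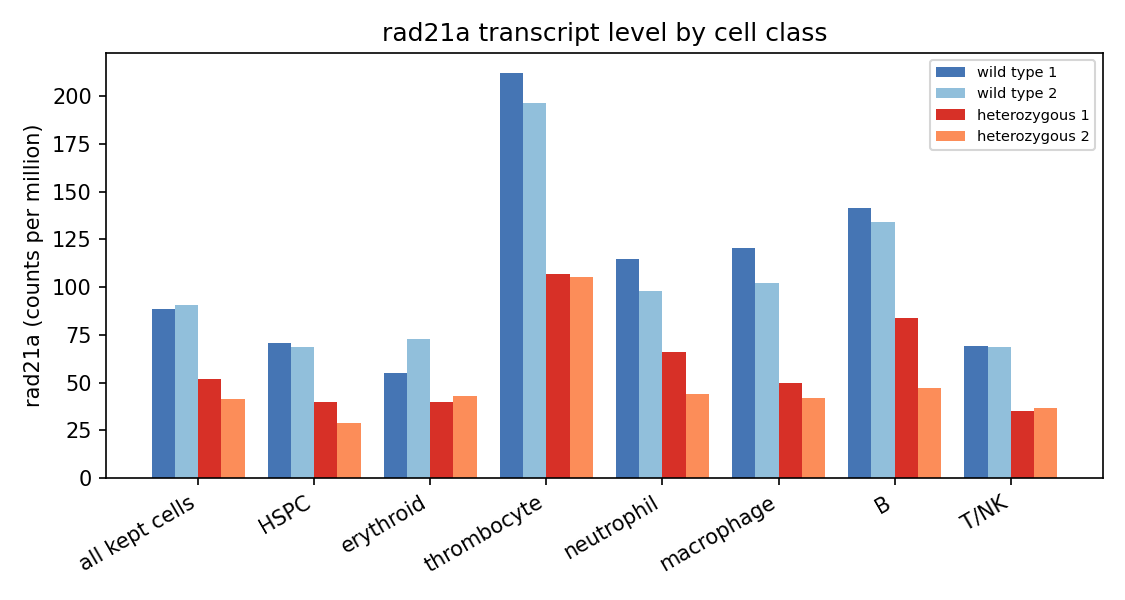
Bars show rad21a (CPM) in each of the 4 libraries (2 wild type in blue, 2 heterozygous in red and orange), over all kept cells and in each class. In every group both heterozygous bars are below both wild type bars, as in all kept cells, with 51.6 and 41.4 against 88.6 and 90.4.

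The composition of the marrow was compared next. HSPC-like cells made up 4.81% and 4.56% of kept cells in wild type and 6.0% and 8.44% in heterozygous libraries, a mean of 4.68% ± 0.179 (SD, n = 2) against 7.22% ± 1.72. Thrombocyte-like cells also lay above both wild types, at 1.96% and 1.43% against 2.30% and 2.62%. Neutrophil-like cells lay below, at 28.2% and 33.2% against 22.4% and 27.2%. With doublets kept, where cells were clustered and named anew, their heterozygous mean was 1.05 percentage points above the wild type mean. Neutrophil-like cluster 5 of the main setting had passed the minimum score of 0.3 at 0.37. In the alternative with doublets kept, a low-UMI cluster led by lyz (2260 cells, median 612 UMIs) stayed unnamed because its score was low (0.27). The mean unnamed share of wild type was 15.2% there, against 7.24% in the main setting. Erythroid-like cells stood at 32.3%, 21.8%, 25.8% and 28.1%, in wild type mainly in clusters 10 and 11, while cluster 16 was the largest in heterozygous libraries (4.27%, 1.78%, 13.9% and 12.1% of kept cells). Macrophage-like cells stood at 10.4% and 11.9% against 19.8% and 9.19%, the third value being the library that holds cluster 32.

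For the shares of HSPC-like, thrombocyte-like and neutrophil-like cells the exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. edgeR on cell numbers passed 0 of the groups of cells and 0 at an unadjusted p under 0.05 (smallest adjusted p 0.398; HSPC-like log2 fold change 0.63). B-cell-like cells held 8.01%, 9.03%, 8.73% and 11.2% of kept cells and T/NK-like cells 7.27%, 7.5%, 6.61% and 7.37%, with overlapping genotypes in the main setting. The T/NK-like share was 11.01%, 9.787%, 5.943% and 7.245% with at least 500 genes per cell. It was 9.837%, 9.718%, 7.148% and 7.968% without clusters of low UMI count. In both alternatives the heterozygous libraries lay below both wild types. The T/NK-like genotypes overlapped without clusters held by 1 library (difference 0.163 percentage points). Wild type libraries held more cells of low UMI count. With at least 500 genes per cell the HSPC-like share was 9.27% and 8.47% in wild type and 7.81% and 9.11% in heterozygous libraries. Cells were clustered and named anew there. A cluster led by mki67 (811 cells) was HSPC-like, and one led by mycb (1176 cells) was unnamed, while mycb led HSPC-like cluster 22 in the main setting. That share therefore does not concern the same cells as the main one. Without clusters of low UMI count the genotypes overlapped, at 6.51%, 5.91%, 6.50% and 9.12% for HSPC-like, 2.66%, 1.86%, 2.49% and 2.83% for thrombocyte-like and 25.9%, 31.3%, 23.8% and 26.5% for neutrophil-like cells. The difference in percentage points with each library left out in turn ranged from 1.32 to 3.76 for HSPC-like, 0.495 to 1.03 for thrombocyte-like and -8.44 to -3.38 for neutrophil-like cells. With a class for each cell from its own marker score, the thrombocyte-like share was lower in heterozygous libraries (-2.10 percentage points).

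**Figure D2:**
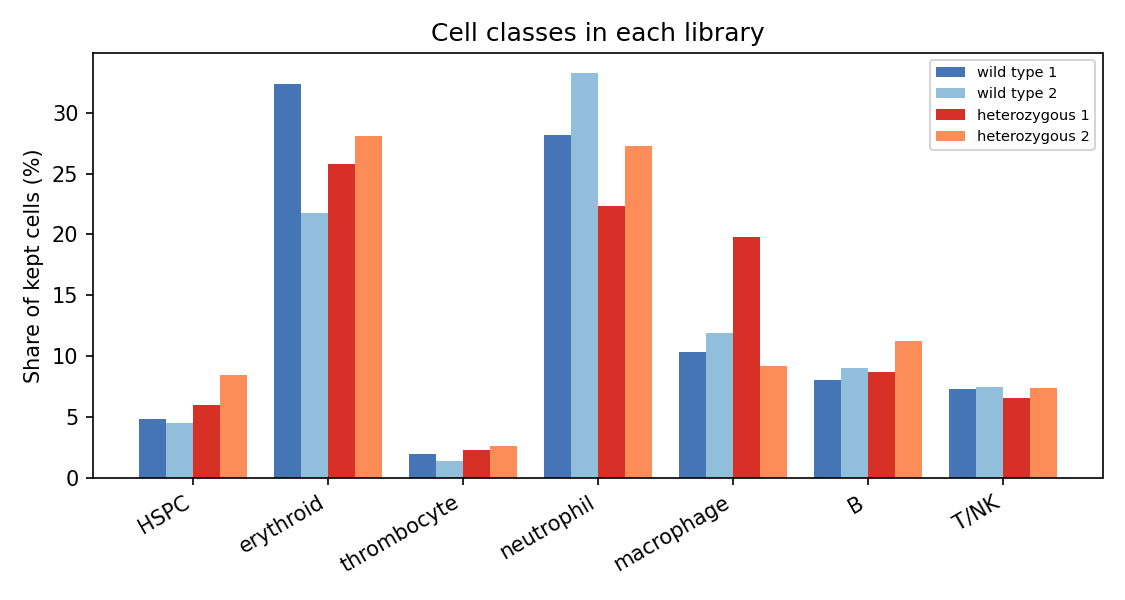
Bars show the share of kept cells (percent) of each of the 7 classes in the 4 libraries (2 wild type in blue, 2 heterozygous in red and orange). The HSPC bars are 4.81 and 4.56 in wild type and 6.0 and 8.44 in heterozygous libraries, and the macrophage bar of heterozygous replicate 1 stands at 19.8.

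**Figure D3:**
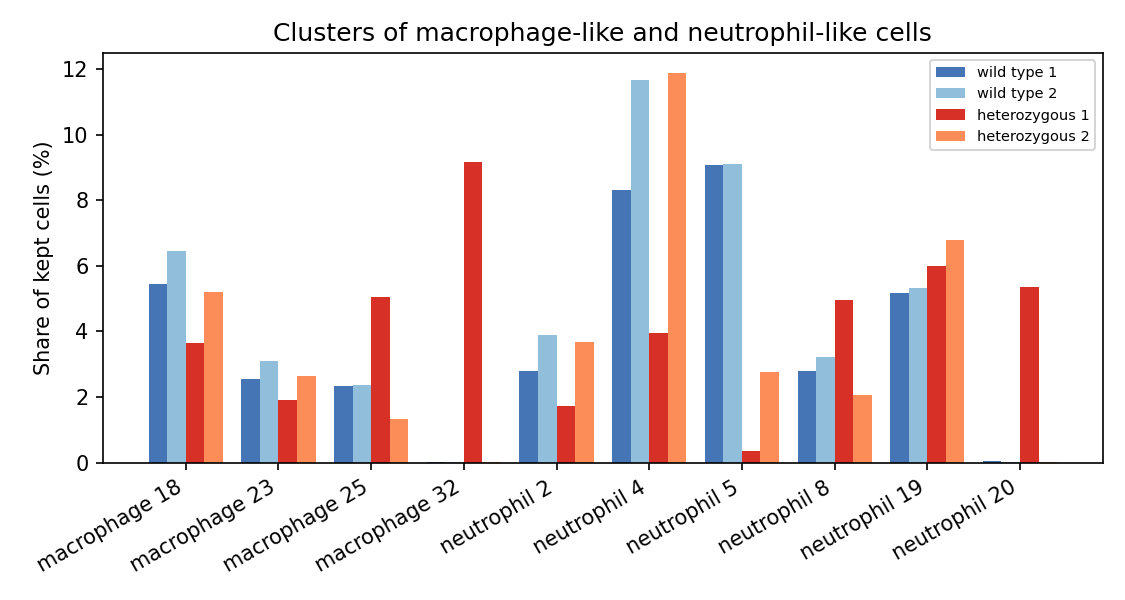
Bars show the share of kept cells (percent) of each macrophage-like and neutrophil-like cluster in the 4 libraries (2 wild type in blue, 2 heterozygous in red and orange). Cluster 32 (9.16) and cluster 20 (5.36) stand out in heterozygous replicate 1 and are close to 0 in the others, while cluster 5 is larger in wild type, at 9.06 and 9.11.

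Over all kept cells, a bulk-like view of the marrow, the lists of heme synthesis, S phase and heat shock genes had medians above 0 in heterozygous libraries and were called by camera, but not with an estimated correlation. The chaperone gene hsp90aa1.2 (ENSDARG00000024746) stood at 57.7 and 87.3 CPM in wild type and 202 and 207 CPM in heterozygous libraries (log2 fold change 1.44, SE 0.28). Also higher were cpox (ENSDARG00000062025; 1.25), the heme enzyme gene for coproporphyrinogen oxidase, mthfd2 (ENSDARG00000098646; 1.11) of mitochondrial folate metabolism, and higd1a (ENSDARG00000022303; 1.09). Lower were the stress-responsive sestrin gene sesn1 (ENSDARG00000020693; -1.37, SE 0.29; 138, 109, 45.2 and 53.8 CPM), timp4.3 (ENSDARG00000100795; -1.46), the mannose receptor gene mrc1b (ENSDARG00000038822; -1.22) and gbp (ENSDARG00000040059; -1.17), which lies within the 100 tested genes on 1 side of rad21a on the reference. The lipid genes fabp11a (ENSDARG00000017299; -2.90) and g0s2 (ENSDARG00000078859; -3.79) and cd9b (ENSDARG00000016691; -2.68) were lower too. These 3 genes are among the leading genes of unnamed cluster 26, which held 1.16%, 0.630%, 0.196% and 0.272% of kept cells.

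For counts of list members above or below both wild type libraries, 16.7% on each side is the share for exchangeable libraries. The libraries differ in UMIs per cell and members of a list can move together. The share over all tested genes is not given here, so these counts, here and below, do not show an excess over chance. In the list of heme synthesis and erythroid genes, 9 of 26 members were above both wild type libraries and 1 below both, with a median log2 fold change of 0.65. Examples are hmbsb at 34.3, 24.9, 63.2 and 69.6 CPM, and the erythroid transcription factor gata1a at 20.9, 14.6, 33.8 and 36.5 CPM. Within erythroid-like cells the median of this list was 0.11, and over all kept cells markers of classes moved as well, with medians of 0.63 for erythroid, -0.78 for T-cell, -0.47 for B-cell and -0.50 for dendritic markers. In the S phase list 29 of 41 members were above both wild type libraries, such as the replication clamp gene pcna at 180, 209, 344 and 237 CPM and hells at 34.1, 44.6, 68.3 and 47.7 CPM (median 0.26). In the heat shock list 11 of 22 were above both, such as dnajb1b at 9.81, 11.6, 18.5 and 23.9 CPM and hsp70.3 at 1.33, 6.26, 18.3 and 43.4 CPM (median 0.46). With limma camera the adjusted p was 1.56e-06, 4.68e-06 and 1.07e-05 for these lists, and adjusted p = 0.898, 0.898 and 0.512 with an estimated correlation. With edgeR 0 of their members passed over all genes, and 0 passed adjusted over the list alone. The members cpox and hsp90aa1.2, named above, passed DESeq2's threshold. Without heterozygous replicate 2 the camera p of the heme list was 0.212. In all, 11 of 25 lists were called by camera, 7 higher and 4 lower, and 0 with an estimated correlation or with fry. Without wild type replicate 2 the count was 7.

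All genes named for this bulk-like view, apart from the examples given for lists, passed DESeq2's threshold, as 66 genes did (17 higher, 49 lower). This does not cover the other cohesin genes given with rad21a. edgeR passed 0 of 15830 genes, with 790 at an unadjusted p under 0.05. Without wild type replicate 1 edgeR passed 15 genes, and without wild type replicate 2 it passed 2.

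In HSPC-like cells, the second question was which genes differ within the compartment that feeds all lineages. Among genes with a symbol and a mean of at least 20 CPM that passed DESeq2's threshold, the largest fold change was that of tsc22d3 (ENSDARG00000075666), known as the glucocorticoid-induced leucine zipper gene, at 54.4 and 37.8 CPM in wild type and 10.1 and 9.97 CPM in heterozygous libraries (log2 fold change -2.39, SE 0.29). The kinase gene mknk2b (ENSDARG00000015164; -1.72), sesn1 (-1.61), the antiproliferative gene btg1 (ENSDARG00000027249; -1.33, SE 0.30), the mitochondrial carrier gene ucp2 (ENSDARG00000043154; -1.23) and icn (ENSDARG00000009978; -1.21) were lower as well. The value of rgcc (ENSDARG00000035810), a regulator of the cell cycle, was -1.47 (189, 156, 75.7 and 67.6 CPM). It was 0.16 with at least 500 genes per cell, where cells were clustered and named anew. These genes passed DESeq2's threshold (adjusted p from 3.44e-07 for tsc22d3 to 0.0497 for ucp2), not edgeR's. Among them, icn is a leading gene of neutrophil-like cluster 5.

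Of 88 genes of the ribosomal list, 35 were below both wild type libraries and 4 above, with a median log2 fold change of -0.30. Without the genes of kinases and binding proteins the median was -0.31 over 79 genes. An example is rpl35 at 8550, 7871, 6612 and 7539 CPM, while rps3, also among the 4 members with the smallest p, overlapped between genotypes at 4739, 4210, 3331 and 4248 CPM; their log2 fold changes were 0.10 and 0.05 with at least 500 genes per cell, where the median of the list was 0.15. Heat shock genes were higher, with 5 of 16 above both wild types (median 0.72), such as dnajb1b at 4.54, 5.57, 18.5 and 10.9 CPM. Cholesterol synthesis genes were higher, with 6 of 14 above both (median 0.34), such as idi1 at 4.65, 3.26, 13.9 and 7.94 CPM. The medians of these 2 lists were 0.41 and 0.12 with at least 500 genes per cell. That alternative clustered and named cells anew, so its values do not concern the same HSPC-like cells. The camera adjusted p was 7.6e-07, 0.00355 and 0.0235, and adjusted p = 0.927 with an estimated correlation for each. Adjusted over the list alone, 0, 1 and 0 members passed. The camera p was 0.153, 0.281 and 0.163 without heterozygous replicate 1, and 0.205 for cholesterol synthesis without wild type replicate 1. Markers of neutrophils were also lower in this class (median -0.43 over 13 genes, camera adjusted p 0.0114; adjusted p = 0.555 with an estimated correlation; camera p 0.0821 without heterozygous replicate 2 and 0.186 without wild type replicate 1). The 31 haematopoietic transcription factor genes had a median of 0.04 (camera adjusted p 0.983), with 6 above and 8 below both wild types, and a median of 0.43 with at least 500 genes per cell.

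edgeR passed 0 of 10022 genes in HSPC-like cells, with 579 at an unadjusted p under 0.05, and DESeq2 passed 25. Without heterozygous replicate 2 edgeR passed 964 genes, without heterozygous replicate 1 it passed 76, without wild type replicate 2 it passed 5 and without wild type replicate 1 it passed 1.

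Erythroid-like cells had the most genes with a small p. Among genes that passed DESeq2's threshold, icn stood at 291, 386, 49.0 and 80.9 CPM (log2 fold change -2.71, SE 0.31), lyz (lysozyme; ENSDARG00000057789) at 4018, 3340, 634 and 1816 CPM (-1.95, SE 0.49), and lect2l (ENSDARG00000033227; -1.99), npsn (ENSDARG00000010423; -1.69), alox5ap (ENSDARG00000054755; -2.03) and tmsb1 (ENSDARG00000104181; -1.96) were lower as well. fabp11a (-2.32) and sesn1 (-1.84, SE 0.32) were also lower. Of these lower genes, icn, lyz and lect2l are leading genes of neutrophil-like cluster 5, and npsn of neutrophil-like cluster 4. Whether these transcripts came from other cells was not tested. Higher were tars (threonyl-tRNA synthetase; ENSDARG00000013250; 1.73, SE 0.38; 24.1, 35.8, 166 and 80.5 CPM), psat1 (serine synthesis; ENSDARG00000016733; 1.7, SE 0.25), gtpbp1 (ENSDARG00000053467; 1.28), odc1 (polyamine synthesis; ENSDARG00000007377; 1.21), higd1a (1.07), cpox (1.06, SE 0.24), chchd2 (ENSDARG00000059304; 1.04) and bcl2l10 (ENSDARG00000026766; 1.04). Cluster 16 held a larger share of the heterozygous than of the wild type libraries, and clusters 10 and 11 a smaller one, and the median UMI count per cell was 4040.5, 2536, 7194 and 8439.

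Of the 16 neutrophil granule and oxidase genes, 13 were below both wild type libraries and 0 above, with a median of -1.58. Adjusted over the list alone 12 passed, among them nccrp1 (-1.58), timp2b (-1.91), cyba (-1.33) and rac2 (-1.23). Neutrophil markers in general had a median of -1.63 in these erythroid-like cells (9 of 13 passed adjusted over the list alone) and B-cell markers -1.02 (4 of 5). Cholesterol synthesis genes were higher, with 12 of 19 above both wild types and 1 below, such as hmgcs1 at 2.71, 2.84, 13.6 and 6.28 CPM and msmo1 at 0.618, 0.632, 2.08 and 1.98 CPM. 1 passed adjusted over the list alone, hmgcra, which had 0 counts in both wild type libraries. Heat shock genes were higher, with 13 of 19 above both and 4 passing adjusted over the list alone (median 0.50), such as dnajb1b at 3.75, 6.63, 16 and 41.4 CPM and hsp70.2 at 0.238, 1.66, 11.2 and 46.2 CPM. For these lists the camera adjusted p was 2.36e-12, 1.38e-05 and 4.06e-05, and adjusted p = 0.402, 0.402 and 0.476 with an estimated correlation. In all, camera called 10 of 23 lists in this class, 5 higher and 5 lower, and 6 without clusters of low UMI count. With an estimated correlation or with fry 0 were called. Next by p were the unfolded protein and amino acid response (median 0.42, 4 of 25 passed adjusted over the list alone, camera adjusted p 5.24e-05; adjusted p = 0.402 with an estimated correlation), and the ribosomal list (median -0.34, camera adjusted p 5.17e-05; adjusted p = 0.869 with an estimated correlation; camera p 0.762 without wild type replicate 1).

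edgeR passed 0 of 10035 genes in erythroid-like cells (1222 at an unadjusted p under 0.05, smallest adjusted p 0.0668), and DESeq2 passed 186, 50 higher and 136 lower. With the replicate number as a block edgeR passed 221 genes, and with summed counts thinned to equal depth 52. edgeR passed 26 without wild type replicate 1, 69 without wild type replicate 2, 14 without heterozygous replicate 1 and 1 without heterozygous replicate 2.

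In thrombocyte-like cells, the clotting cells of fish, 2 genes passed with edgeR, and both are immunoglobulin genes that lead B-cell-like cluster 12. They were igic1s1 (ENSDARG00000093272) at 49.3, 64.5, 7.01 and 6.47 CPM (log2 fold change -3.14, SE 0.41, edgeR adjusted p 0.0172) and CU571382.1 (ENSDARG00000069839) at 26.4, 35.0, 0 and 0.924 CPM (edgeR adjusted p 0.0172). Genes of protein folding in the endoplasmic reticulum were higher: in the unfolded protein and amino acid response list 10 of 20 members were above both wild types and 0 below (median 0.48). The chaperone gene hspa5 (BiP; ENSDARG00000103846) stood at 58.4, 74.3, 269 and 176 CPM and manf at 37.8, 46.2, 145 and 73.0 CPM, and 2 members passed adjusted over the list alone.

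Neutrophil granule and oxidase genes were lower here too, with 11 of 14 below both wild types (median -0.61, 2 passing adjusted over the list alone), such as cybb at 13.7, 42.0, 9.01 and 4.62 CPM. Neutrophil markers had a median of -0.87 in this class (5 of 10 adjusted over the list alone). G2 and mitosis genes had a median of 0.25, with 11 of 37 above both wild types and 2 below, such as plk1 at 29.8, 26.6, 64.1 and 46.2 CPM. The camera adjusted p was 1.99e-06 for granule, 0.000227 for protein folding and 0.00523 for mitosis genes, and adjusted p = 0.684 with an estimated correlation for each. Without wild type replicate 1 the p for mitosis genes was 0.278. The B-cell receptor list was called lower (camera adjusted p 0.00523; adjusted p = 0.684 with an estimated correlation) with a mean of -1.16 but a median of 0.08 over 7 genes, 3 of which passed adjusted over the list alone. Of 5858 genes tested, 292 had an unadjusted p under 0.05, and DESeq2 passed 0. edgeR passed 6 genes without either wild type library, 59 without heterozygous replicate 1, 407 without heterozygous replicate 2, 1 with doublets kept and 0 with at least 500 genes per cell.

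In neutrophil-like cells, mhc2a (ENSDARG00000031745), an MHC class II gene, was at 108, 135, 47.5 and 47.8 CPM (log2 fold change -1.50, SE 0.30) and prune2 (ENSDARG00000059423) at 36.9, 30.2, 7.47 and 13 CPM (-1.80, SE 0.40). Both passed DESeq2's threshold (adjusted p 0.0148 and 0.0194), not edgeR's. Markers of other classes had medians of -0.83 (B-cell), -0.32 (macrophage) and -0.37 (HSPC) in these cells. With at least 500 genes per cell these were 0.06, 0.003 and -0.07. The MHC class II list stood at -0.37 and then at -0.34, and the interferon list at -0.37 and then at -0.40. Genes of oxidative phosphorylation were higher, with 35 of 96 above both wild types and 3 below (median 0.25), such as ndufb5 at 76.2, 73.4, 160 and 91.2 CPM. Genes of the ribosomal list were lower, with 57 of 89 below both and 3 above (median -0.28), such as rps8a at 4594, 3993, 3536 and 3652 CPM. Without the genes of kinases and binding proteins the median was -0.29 over 79 genes. Interferon response genes were lower, with 15 of 28 below both and 2 above (median -0.37), such as stat1b at 2.87, 4.95, 0.562 and 0.129 CPM, the 1 member that passed adjusted over the list alone.

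The camera adjusted p was 1.85e-06 for oxidative phosphorylation, 8.06e-06 for ribosomal and 0.000273 for interferon genes, and adjusted p = 0.626 with an estimated correlation for each. The p was 0.558 for oxidative phosphorylation without heterozygous replicate 1 and 0.0963 for interferon genes without wild type replicate 2. edgeR passed 0 of 11397 genes in neutrophil-like cells, with 388 at an unadjusted p under 0.05, and DESeq2 passed 21. Without wild type replicate 1 edgeR passed 8, without wild type replicate 2 it passed 1, without heterozygous replicate 1 it passed 9 and without heterozygous replicate 2 it passed 162.

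In macrophage-like cells, f13a1a.1 (ENSDARG00000045453), a gene for the coagulation factor XIII A chain, stood at 118 and 99.8 CPM in wild type and 2.89 and 6.03 CPM in heterozygous libraries (log2 fold change -4.66, SE 0.45), and s100w (ENSDARG00000101181) at 51.2, 51.6, 7.59 and 17.3 CPM (-2.07, SE 0.45). Higher were the retinol-binding protein gene rbp2a (ENSDARG00000070038) at 5.01, 2.02, 87.8 and 48.8 CPM (4.23, SE 0.50), arl11 (ENSDARG00000036637; 1.60) and iscub (ENSDARG00000026582; 1.43). mfap4 (ENSDARG00000090783), at 206, 553, 2512 and 1066 CPM (2.16), is also a leading gene of cluster 32, which only heterozygous replicate 1 holds in number. These genes passed DESeq2's threshold (adjusted p from 1.76e-23 for f13a1a.1 to 0.0494 for iscub), not edgeR's.

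G2 and mitosis genes were lower, with 24 of 39 below both wild types and 0 above (median -0.55), such as cenpf at 91.6, 70.0, 56.2 and 40.5 CPM and nusap1 at 71.7, 72.5, 49.2 and 36.5 CPM. With at least 500 genes per cell, where cells were clustered and named anew, the median of the list was 1.303. Heme synthesis and erythroid genes were higher, with 13 of 23 above both wild types (median 0.45), such as slc4a1a at 31.2, 21.7, 60.4 and 39.2 CPM, and erythroid markers had a median of 0.49 in these cells. Mitochondrially encoded genes had a median of 0.47 with 6 of 13 above both, but the 4 members with the smallest p overlapped between genotypes, such as mt-atp6 at 3014, 4298, 7407 and 4228 CPM. The camera adjusted p was 9.6e-12, 3.23e-05 and 0.000534 for these lists, and adjusted p = 0.892 with an estimated correlation for each, and 0 members passed adjusted over the list alone. For mitochondrially encoded genes the p was 0.112 without heterozygous replicate 1 and 0.351 without wild type replicate 1.

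edgeR passed 0 of 11873 genes in macrophage-like cells (638 at an unadjusted p under 0.05), and 4 without the clusters held by 1 library, while DESeq2 passed 19. Without heterozygous replicate 2 edgeR passed 1108 genes, without heterozygous replicate 1 it passed 56 and without wild type replicate 1 it passed 6.

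B-cell-like cells had 1 gene by the rule, fkbp5 (ENSDARG00000028396), a glucocorticoid-induced co-chaperone gene, at 48.3, 25.8, 4.59 and 3.14 CPM (log2 fold change -3.31, SE 0.44; DESeq2 adjusted p 0.000278, edgeR 0.0884). Genes of Myc activity and ribosome biogenesis were higher, with 18 of 33 above both wild types and 0 below (median 0.41), such as rrs1 at 20.5, 25.5, 63.8 and 27.3 CPM and polr1d at 18.0, 28.6, 51.4 and 31.4 CPM. G2 and mitosis genes were lower, with 17 of 38 below both and 0 above (median -0.50), such as knstrn at 22.5, 27.7, 21.6 and 11.6 CPM. Globin transcripts, which B cells do not make, were lower, with 3 of 5 below both wild types (median -0.61), such as hbba2 at 3073, 2586, 1501 and 2232 CPM, with a log2 fold change of 0.08 at a minimum of 500 genes per cell.

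The camera adjusted p was 7.18e-08 for Myc, 1.85e-09 for mitosis and 0.0124 for globin genes, and adjusted p = 0.819 with an estimated correlation for each, and 0 members passed adjusted over the list alone. For mitosis genes the p was 0.925 without heterozygous replicate 2, and for globins 0.768 without heterozygous replicate 1 and 0.0593 without wild type replicate 1. edgeR passed 0 of 8454 genes in B-cell-like cells, with 286 at an unadjusted p under 0.05, and DESeq2 passed 3. Without a library edgeR passed 37 (wild type replicate 1), 1 (wild type replicate 2), 140 (heterozygous replicate 1) and 385 (heterozygous replicate 2).

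In T/NK-like cells fkbp5 fell, from 70.08 and 49.5 CPM to 10.2 and 8.18 CPM (log2 fold change -2.74, SE 0.30, edgeR adjusted p 0.0167). The other gene that passed with edgeR, si:ch211-5k11.8 (ENSDARG00000079078; -1.79, SE 0.22, adjusted p 0.0255; 13163, 9459, 3325 and 3420 CPM), is the first leading gene of erythroid-like cluster 10. Genes that passed with DESeq2 alone were also lower: the metabolic kinase gene pdk2b (ENSDARG00000059054; -2.16), arrdc3b (ENSDARG00000036028; -1.55), mknk2b (-1.28) and btg1 (-0.99), and the neutrophil genes mpx (ENSDARG00000019521; -1.34) and npsn (-1.21).

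Neutrophil granule and oxidase genes were lower in T/NK-like cells, with 10 of 16 below both wild types and 5 passing adjusted over the list alone (median -0.79), and neutrophil markers had a median of -0.80. G2 and mitosis genes had a median of 0.40, with 7 of 24 above both wild types, such as nusap1 at 3.45, 13.2, 21.9 and 21.0 CPM. Myc and ribosome biogenesis genes were higher, with 16 of 33 above both and 1 below (median 0.27), such as nhp2 at 56.3, 73.9, 105 and 101 CPM. The camera adjusted p was 7.49e-06, 1.25e-05 and 0.00162 for these lists, and adjusted p = 0.981 with an estimated correlation for each. For mitosis genes the p was 0.087 without heterozygous replicate 1 and 0.313 without wild type replicate 1, and for Myc genes 0.101 and 0.215. Of 7687 genes, edgeR passed 2, with 388 at an unadjusted p under 0.05, and DESeq2 passed 12. With the replicate number as a block edgeR passed 0 (smallest adjusted p 0.0653), so neither of its 2 genes passed there. edgeR passed 48 without wild type replicate 1, 44 without wild type replicate 2, 0 without heterozygous replicate 1 and 1, a higher gene, without heterozygous replicate 2.

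Whether the genotype effect differed between classes was tested for 4 pairs. Between HSPC-like and neutrophil-like cells the largest differences by p were those of tsc22d3, at -2.39 in HSPC-like and -0.28 in neutrophil-like cells (difference 2.09, SE 0.29), and of mhc2a, at 0.12 and -1.50 (difference -1.60, SE 0.23), both with an edgeR adjusted p of 0.179. Between HSPC-like and erythroid-like cells mknk2b stood at -1.72 and 0.06 (difference 1.81, SE 0.31) and arrdc3b at -0.59 and 1.53 (difference 2.12, SE 0.38), each with an adjusted p of 0.131. Between B-cell-like and T/NK-like cells clic2 stood at 0.92 and -1.59 and sh2d1ab at -2.87 and -0.11, each with an adjusted p of 0.0735. Between neutrophil-like and macrophage-like cells hmox1a, for heme oxygenase, stood at -0.65 and 1.05 (difference 1.73, SE 0.31, adjusted p 1). These genes were chosen after their values were seen.

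edgeR passed 0 genes in each pair, with 484, 679, 386 and 437 at an unadjusted p under 0.05 in the order given, and DESeq2 passed 2, 13, 0 and 0. With wild type replicate 1, wild type replicate 2, heterozygous replicate 1 or heterozygous replicate 2 left out, edgeR passed 9, 14, 0 and 21 genes for HSPC-like with neutrophil-like, 11, 21, 246 and 343 for HSPC-like with erythroid-like, 21, 16, 4 and 61 for B-cell-like with T/NK-like, and 1, 7, 14 and 648 for neutrophil-like with macrophage-like cells.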

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

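The comparison of list medians between classes, and the medians with at least 500 genes per cell, were chosen after the data were seen.

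A pair of gene lists moved in opposite directions in different classes, in both heterozygous libraries of each class against the wild type mean, and the difference between the classes was not tested. The list of G2 and mitosis genes had a median log2 fold change of 0.2536 in thrombocyte-like cells (11 of 37 members above both wild type libraries) against -0.547 in macrophage-like cells (24 of 39 below both). With at least 500 genes per cell the medians were 0.28 and 1.303 (35 of 37 members above 0 in macrophage-like cells), so the opposite direction was lost there. Cells were clustered and named anew in that alternative, and a cluster led by mki67 (811 cells) was HSPC-like. In HSPC-like cells the median of this list moved from 0.29 to -0.67. The effect of the filter and that of the new classes cannot be told apart. The list of glycolysis genes had a median of 0.2318 in neutrophil-like cells (9 of 23 above both) against -0.3488 in thrombocyte-like cells (5 of 18 below both), and 0.20 against -0.43 with at least 500 genes per cell. Without wild type replicate 1 the limma camera adjusted p was 0.278 for both lists in thrombocyte-like cells and 0.244 for glycolysis in neutrophil-like cells; without heterozygous replicate 2 it was 0.0909 for glycolysis in thrombocyte-like and 0.446 in neutrophil-like cells. None of these list calls passed with an estimated correlation (adjusted p = 0.684 in thrombocyte-like, 0.892 in macrophage-like and 0.626 in neutrophil-like cells with an estimated correlation).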

How the results depend on the processing

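The alternatives without clusters held by 1 library or of low UMI count, the list medians with at least 500 genes per cell, and the libraries left out in the tests between classes, were chosen after the data were seen. A fit with 1 library left out has 1 genotype with a single library, which is assumed to vary like the other genotype. The direction of rad21a was kept in every alternative run, while the numbers of genes past the threshold in single classes changed by over 1.5 times in 54 cases and stayed within that in 37. For all kept cells these were 4 and 9, and for lists 28 and 52. Causes were not tested. RLE normalization moved none of the counts of genes by over 1.5 times. Nothing in the sources used here says whether equal replicate numbers pair the pools, and this stays open. The correlation across genes of replicate deviations between the genotypes lay between -0.213 and 0.281. In simulated data with the depths and spreads of these libraries edgeR recovered at most 20.9% of genes changed 2-fold.

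Counts of genes are given for all kept cells and then for HSPC-like, erythroid-like, thrombocyte-like, neutrophil-like, macrophage-like, B-cell-like and T/NK-like cells. DESeq2 passed 66, 25, 186, 0, 21, 19, 3 and 12 genes, and edgeR without a filter on low counts 2, 117, 557, 27, 203, 6, 45 and 109. With the replicate block edgeR passed 12 in HSPC-like, 221 in erythroid-like, 28 in thrombocyte-like, 3 in neutrophil-like, 22 in B-cell-like and 0 in T/NK-like cells. With sums thinned to equal depth it passed 52 in erythroid-like, 2 in B-cell-like and 4 in T/NK-like cells. With doublets kept it passed 1 in thrombocyte-like cells, with at least 500 genes per cell 0 in thrombocyte-like and 1 in B-cell-like cells, and without clusters held by 1 library 4 in macrophage-like cells. With each library left out the counts ranged from 0 to 15 in all kept cells, 1 to 964 in HSPC-like, 1 to 69 in erythroid-like, 6 to 407 in thrombocyte-like, 1 to 162 in neutrophil-like, 0 to 1108 in macrophage-like, 1 to 385 in B-cell-like and 0 to 48 in T/NK-like cells. In HSPC-like, thrombocyte-like, neutrophil-like, macrophage-like and B-cell-like cells the highest count was that without heterozygous replicate 2.

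For differences between classes, DESeq2 passed 2 (HSPC-like with neutrophil-like) and 13 (HSPC-like with erythroid-like). Without a filter the counts were 60, 87, 14 (neutrophil-like with macrophage-like) and 17 (B-cell-like with T/NK-like), and with thinned sums 2 and 8 in the pairs with HSPC-like cells. With each library left out they ranged from 0 to 21, 11 to 343, 1 to 648 and 4 to 61.

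Lists called by limma camera numbered 0 with an estimated correlation and 0 with fry in all kept cells and in HSPC-like, erythroid-like, thrombocyte-like, neutrophil-like, macrophage-like, B-cell-like and T/NK-like cells. With each library left out they ranged from 7 to 12 in all kept cells, 2 to 12 in HSPC-like, 6 to 13 in thrombocyte-like, 7 to 13 in neutrophil-like, 4 to 12 in B-cell-like and 2 to 6 in T/NK-like cells. With at least 500 genes per cell the median log2 fold change of a list changed sign for ribosomal genes in HSPC-like (0.15), the B-cell receptor list in thrombocyte-like (from 0.08 to -0.90), mitosis genes in macrophage-like (1.303) and globins in B-cell-like cells (0.0825), among the lists described above. It also did so for mitosis genes in HSPC-like cells (from 0.29 to -0.67). In neutrophil-like cells it did so for B-cell markers (from -0.83 to 0.06) and macrophage markers (from -0.32 to 0.003). By camera HSPC-like cells had 3 with the replicate block, and erythroid-like cells 6 without clusters of low UMI count.

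The rad21a change passed the threshold in these alternatives: DESeq2 in all kept cells (-1.01), HSPC-like (-1.23), erythroid-like (-0.92) and macrophage-like cells (-1.33), no filter in HSPC-like (-1.23), erythroid-like (-0.92) and T/NK-like cells (-0.99), and the replicate block in erythroid-like cells (-0.95). With each library left out it ranged from -1.35 to -1.17 in HSPC-like, -1.13 to -0.93 in thrombocyte-like, -1.43 to -1.23 in macrophage-like and -1.44 to -0.90 in B-cell-like cells, with some of these past the threshold in each of these classes.

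Differences of shares (percentage points, heterozygous minus wild type) changed sign as follows. With at least 500 genes per cell they were -0.405 for HSPC-like, 11.2 for erythroid-like and -3.81 for B-cell-like cells. Without clusters held by 1 library they were 2.08 for erythroid-like, -0.325 for macrophage-like and 0.163 for T/NK-like cells, and without clusters of low UMI count 7.48 for erythroid-like and -0.473 for B-cell-like cells. The erythroid-like difference was 0.121 and 3.29 at Leiden resolutions 0.5 and 2, 0.351 with all deposited barcodes, 1.60 with cells thinned to equal depth and 2.69 from each cell's own marker score, which gave -2.10 for thrombocyte-like cells. Neutrophil-like cells were at 1.05 with doublets kept, where a low-UMI cluster led by lyz stayed unnamed. With each library left out the range was -5.39 to 5.18 for erythroid-like and -1.95 to 8.64 for macrophage-like cells.

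Log2 fold changes of single genes changed sign as follows. In all kept cells, cdca5 was at 0.000546 with DESeq2 and 0.11 without clusters held by 1 library; nipbla at 0.00274 with DESeq2, 0.0020 with at least 500 genes per cell, 0.00423 without clusters held by 1 library and 0.00688 without clusters of low UMI count; pds5a at -0.025 with at least 500 genes and -0.00683 without clusters of low UMI count; hdac8 (ENSDARG00000003021) at -0.12 and waplb at -0.0415 without clusters held by 1 library. Their ranges with each library left out were -0.25 to 0.17 (cdca5), -0.15 to 0.10 (nipbla), -0.042 to 0.14 (nipblb), -0.0935 to 0.10 (pds5a), -0.052 to 0.25 (pds5b), -0.33 to 0.39 (hdac8, ENSDARG00000003021), -0.21 to 0.0221 (hdac8, ENSDARG00000105159), -0.39 to 0.0263 (stag2a), -0.15 to 0.00225 (stag2b), -0.25 to 0.33 (wapla) and -0.0212 to 0.15 (waplb). With at least 500 genes per cell, HSPC-like cells had mvda at -0.48, rgcc at 0.16, rpl23a at 0.044, rpl35 at 0.10, rps18 at 0.0635 and rps3 at 0.0491, macrophage-like cells had bub1bb at 1.25, cenpf at 1.18, cks2 at 0.78 and nusap1 at 1.25, B-cell-like cells had hbaa2 at 0.43 and hbba2 at 0.0825, and erythroid-like cells had mt2 at 0.26 (0.36 without clusters of low UMI count). In macrophage-like cells mt2 was at 0.13 without clusters held by 1 library. With doublets kept hbaa2 was at 0.23 in B-cell-like and mmp13a at 0.00775 in thrombocyte-like cells. With each library left out the range was -0.75 to 0.11 for hbaa2 in B-cell-like cells, and -0.11 to 2.36 for mt-atp8 and -0.0205 to 1.09 for mt-nd3 in macrophage-like cells. Among single genes 2437 of the values under alternatives kept their direction and side of the threshold, 317 passed newly, 13 no longer passed and 44 changed sign.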

Other observations

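The tests of the gene lists written after the data were seen, and the tests of explanations other than that of doublets, were chosen after the result was seen.

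The list of genes that respond to glucocorticoids and that of the fasting and FOXO response had median log2 fold changes below 0 in the 7 classes. fkbp5 was below both wild type libraries in all kept cells and in all 7 classes, at 22.8, 21.9, 3.95 and 1.95 CPM over all kept cells (log2 fold change -3.04, SE 0.29) and with log2 fold changes from -3.99 in erythroid-like to -2.58 in neutrophil-like cells. The FOXO list had a median log2 fold change of -0.96 in HSPC-like cells, where 17 of 28 members were below both wild types and 10 passed adjusted over the list alone, such as arrdc2 at 17.0, 23.9, 5.78 and 5.63 CPM and pik3ip1 at 18.4, 19.7, 5.63 and 5.63 CPM. The median was -0.85 in thrombocyte-like, -0.66 in erythroid-like, -0.50 in neutrophil-like, -0.49 in T/NK-like, -0.44 in B-cell-like and -0.17 in macrophage-like cells. With at least 500 genes per cell it was -0.44 in HSPC-like and -0.48 in thrombocyte-like cells. The glucocorticoid list ranged from -0.28 in neutrophil-like to -1.14 in B-cell-like cells, and with at least 500 genes per cell its median moved from -0.47 to -0.22 in HSPC-like and from -0.64 to -0.21 in erythroid-like cells. Against this direction, sgk1 (1.43), sesn3 (1.01) and bcl6ab (0.97) were higher in macrophage-like cells and arrdc3b (1.53) in erythroid-like cells. Both lists were written after their leading genes had been seen, so their counts are not independent evidence; with an estimated correlation the lowest adjusted p was 0.117.

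The clusters that heterozygous replicate 1 held almost alone shared some raised transcripts and differed in others. The interferon-inducible gene ifitm1 stood at 485 CPM in neutrophil-like cluster 20 against 39.4 CPM in the other neutrophil-like clusters of that library, and at 1310 against 268 CPM in macrophage-like cluster 32. The transferrin gene tfa stood at 171 against 41.0 CPM and at 347 against 42.1 CPM. The serum amyloid gene saa and grn2 were raised in cluster 32 alone, at 1690 against 167 CPM and 10885 against 1657 CPM. In cluster 20 they stood at 6.19 against 5.0 CPM and 257 against 502 CPM. The levels in its other neutrophil-like clusters were themselves raised against the other libraries, where grn2 stood at 3.86 CPM (heterozygous replicate 2) and 60.4 CPM (wild type) and tfa at 0.26 and 0.22 CPM; in other macrophage-like clusters tfa stood at 0.57 and 0.38 CPM.

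These clusters held 1113 cells of heterozygous replicate 1, 14.5% of its kept cells. A shift of all cells of that library stays open: 65.5% of its macrophage-like and neutrophil-like cells lay in clusters shared with other libraries, but the cells in shared clusters also held more tfa than those of the other libraries. The rad21 genotype stays open: the clusters made up 0.0403% of heterozygous replicate 2 (4 cells), but they were chosen as clusters held almost only by 1 library, which by itself allows at most 1.25% there. Doublets stay open, because the median doublet score of cluster 32 lay at percentile 83.9 of the other cells of that library (60.5 for cluster 20), between the bounds set beforehand, and fewer doublets were marked in that library (1.18% of barcodes) than expected (6.78%). A difference between the fish of the pools may be the source and was not tested.

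For the lower glucocorticoid and FOXO genes, the median stayed below 0 without cells of low UMI count, which were more frequent in wild type. In the 3 classes that lose cells without the clusters of low UMI count (erythroid-like, neutrophil-like and macrophage-like) it was -0.31 (bootstrap limits -0.54 to -0.17) without them and -0.36 with them. With at least 500 genes per cell it was -0.40 (-0.55 to -0.25) over all 7 classes, against -0.52 over all kept cells of these classes. The part of such cells stays open, since the FOXO median in HSPC-like cells moved from -0.96 to -0.44 there. The bootstrap draws genes and not libraries, and the lists were written after their leading genes had been seen. Free RNA from other cells stays open: in the class where each of 43 members was most abundant the median log2 fold change was -0.32 (-0.53 to -0.23), but a fall in that class would also lower free RNA in the others. Neutrophil markers, which free RNA can carry, had a median of -0.56 outside neutrophil-like cells. Time of day at collection stays open. A group of clock genes with the arntl, clock and nfil3 genes had a median of 0.03 (6 genes). A group with the per, nr1d, dbp and tef genes had a median of -0.45 (14 genes), 0.48 apart from the first (permutation p = 0.0934 over genes). The rad21 genotype, or a difference in feeding or handling of the fish, may be the cause and was not tested.

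Low p-values (under 0.01) were also more frequent among the neighbours of rad21a on the reference: over all kept cells 7 of 162 neighbours with up to 100 tested genes per side (4.32%), among them gbp, aste1a and nr1d2a, against 0.888% of other genes. Chance clustering along chromosomes stays open, since the smallest share of windows with as many low p-values, 0.497%, multiplied by the 24 fits and window sizes looked at, gives 11.9%. Alleles carried along with the mutation, or reads of variant alleles against the reference, stay open as well: 4 of the 24 fits and window sizes had an enrichment by Fisher's exact test at an adjusted p under 0.05, and in B-cell-like and T/NK-like cells 0 of 50 neighbours at 25 genes per side had a low p. The reference used for the order of genes is a later assembly than that of the counts, and 77.0% of the genes were placed on it.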
